A study of sludge metagenome with 42 samples.

How the data were processed

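Sludge DNA from 6 anaerobic digesters was measured on 42 arrays, 1 for each digester and sampling day. The labels state that genomic DNA was labelled with Cy3 by random priming, and the arrays carried 1 colour. The values are deposited as probe intensity on a linear scale, with empty cells where a probe had no value. The scanner, the background correction, the signal filter and the normalization are not given in the sources used here. The series is also silent on hybridisation batches and on the unit of the organic loading rate. Array totals differed more than 10-fold. The array of co digester 2 on day 62 lay on a higher scale than the others of that day. It had a value for 36637 probes. Of 36106 compared, all but 364 had a log2 ratio of at least 1 to those arrays, at a median of 2.3. The reason is not given. For the other arrays, the totals alone do not show whether all were on 1 scale as deposited. The array with the lowest total also had the fewest probes with a value.

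The file was read as deposited, and 305 negative values on 1 array (mono digester 3 on day 69) were set to missing. Of 55023 probes, 3876 had no value on any array. Signals were summed over all probes of a gene family, with missing values counted as 0, and the log2 of the sum was taken after adding the lowest nonzero family sum (1580.4). Families and probes with a value on at least 9 of 42 arrays were tested, which kept 368 of 371 families and 41880 probes. A probe without a value on an array took the lowest value of that array. Genera with at least 5 probes (916) were summed in the same way. The depth of an array was taken as its summed intensity (210.9 to 3841.7 in units of 1000000 intensity units) and its number of probes with a value (11398 to 43918). No counts exist, so no counting interval was given, and the 3 digesters per arm limit the precision.

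The digester was the replicate. The log2 values of each digester were averaged over the days of a step, which gave 3 values per arm, and the change was the second-step mean minus the first-step mean within each digester. The comparisons were co minus mono at the first step, co minus mono at the second step, and the change in co minus the change in mono digesters, with the change in each arm beside it. The tests were limma 3.58.1 (lmFit, eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05. The prior of eBayes had infinite degrees of freedom for families at the first and second step. Families share a factor per array, so these p-values are too small where whole arrays differ. Detected probes, the Shannon index (natural log), summed signal and organism shares were compared by two-sided exact permutation tests over all 10 splits of the 6 digesters, whose smallest p is 0.1. PERMANOVA on Bray-Curtis dissimilarities of mean relative signals was run with vegan 2.7.1. The data.table package (1.17.8) read the file, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the plots.

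These choices, the gene lists, the organism lists and the rule for named families were fixed before the data were examined. The rule named 33 genes in all comparisons where the file held them (23 were found), up to 6 higher and 6 lower families with the largest log2 difference among those past the threshold that had at least 5 probes and digesters fully separated by arm, and, where fewer than 3 passed in a direction, those with the smallest p up to 3. Not found were mtaB, mtaC, hdrB, dnaK, groEL, katA, copA, czcA, chrA and tet. Families were matched to the lists by name. Of 32 gene lists, 23 held a family and 16 held at least 3 and were tested with camera at a preset correlation of 0.01. camera with an estimated correlation and fry were run beside it. The lists whose names matched no family were hydrogen metabolism, heat shock, oxidative stress, osmotic stress, oxygen limitation, phosphate limitation, nitrogen limitation, zinc and related metals, and tetracycline and vancomycin resistance. A family tetx_resistance was among those tested but under a name not on that list, so tetracycline resistance was not absent from the array (second-step log2 difference 0.16, limma adjusted p = 0.416). The names mer, mch and cdh were left out of the lists after the file was seen, since they were meant for other enzymes than those the file holds under mercury, the 3-hydroxypropionate bicycle and terpenes. The family beta_agarase was left out of osmotic stress, where it had matched betA by the start of its name, after the results were seen. The families limeh, lmo and camdcab, which the file places under terpenes and camphor, stayed in the lignin list as fixed. The 51 categories and subcategories of the file with at least 3 families were tested in the same way.

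The deposited counts of families, probes and genera were recomputed with each array divided by its total, with quantile scaling, and without each digester and each day in turn. The equal-totals counts of the second step and of the change, and the counts of Methanosaeta concilii probes, were recomputed without each digester but not without each day. Counts of gene lists and categories were recomputed only with the other set tests and with equal totals. Other alternatives were the mean log2 of probes present on all arrays, stricter and no filters, a larger pseudocount, missing values left missing, eBayes with trend and robust settings, every array as a value with digester as a random block, and the digester number as a block. The digester numbers carry no pairing in the labels, so the block was not used in the reported tests. Added after the data were seen were the runs without the 5 arrays with fewer than 30000 probes, with and without equal totals, the run without the array of co digester 2 on day 62, the alternatives for genera other than equal totals, and everything on Methanosaeta concilii, Brachybacterium faecium, Corynebacterium ammoniagenes and the array axis. The axis is the first principal component of the 9 first-step co arrays over 10058 probes with a positive value on all arrays, after quantile scaling.

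The procedure was tested on simulated data with 3 digesters per arm and no factor shared by an array. For families at the second step limma recovered 75%, 100% and 100% of changes of 0.5, 1 and 2 on the log2 scale, with 4 false among 59 calls. For probes it recovered 1.5%, 61.2% and 98.5%, with 2 false among 109 calls, and for genera 70.1%, 95.5% and 100%, with 3 false among 180. For the change between steps it recovered 60%, 85% and 95% for families, and 0%, 4.5% and 80.3% for probes.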

Results

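The series asked how functional genes of sludge microbes differ between anaerobic digesters run at different organic loadings. Genomic DNA of sludge was hybridised to a microarray of functional gene probes, each assigned to a gene family and an organism. 3 digesters were fed dairy manure alone at an organic loading rate of 1 (mono digesters). 3 digesters were fed dairy manure and poultry waste (co digesters), at a loading rate of 1.3 on days 62, 66 and 69 (the first step) and of 1.5 on days 83, 87, 90 and 97 (the second step). The unit of the loading rate is not given in the sources used here. Feed and loading differed together, so a difference between the arms belongs to both. Each of the 6 digesters was sampled on all 7 days, which gives 42 arrays. The file held 55023 probes in 371 gene families, and 10058 probes had a positive value on all arrays. The summed signal of an array ran from 210.9 to 3841.7 in units of 1000000 intensity units (median 825.3), and 11398 to 43918 probes had a value. 5 arrays had a value for fewer than 30000 probes: mono digester 1 on days 66, 87 and 90, mono digester 2 on day 87 and co digester 1 on day 66. The 3 digesters per arm limit the precision of comparisons between arms.

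At the first step, the co and mono digesters held nearly the same number of detected probes. Mono digesters had 34212 ± 2980 and co digesters 35515 ± 1996 (SD, n = 3 digesters, exact permutation p = 0.6). The Shannon index of the probe signals was 9.46 ± 0.11 in mono and 9.47 ± 0.20 in co digesters (SD, n = 3, exact permutation p = 0.9). The feed arm took 0.189 of the Bray-Curtis variance between digesters in a permutational test, and 4 of the 10 splits of the 6 digesters gave as much. Without mono digester 1, the difference in detected probes (richness at first step) was -378.

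**Figure D1:**
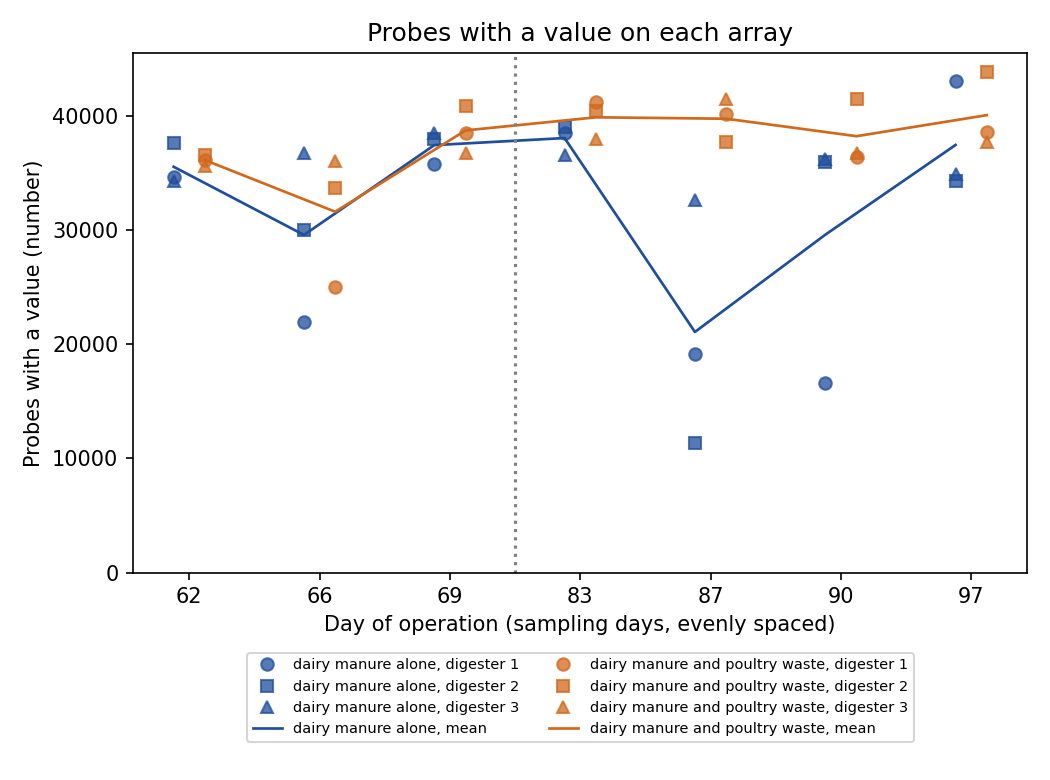
Number of probes with a value on each array (vertical axis) by sampling day (horizontal axis, days evenly spaced), with 1 point per digester and a line through the mean of each arm; the dotted line parts the first from the second step. On day 87 the mono digesters averaged 21093 probes and the co digesters 39784.

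No gene family passed the test at the first step. The families with the smallest p were cpnb (log2 difference, co minus mono, 0.98 ± 0.26 SE, adjusted p = 0.051), pcpA (0.95, 0.051) and the fungal phospholipase B family (0.89, 0.0626), against a median of 0.40 over all 368 families. That median was 0.11 without the array of co digester 2 on day 62, whose total was 4.65 times the median array's, so deposited differences of the first step rest in large part on 1 array. On the lower side the rule named the elongation factor family EF1a_Oxymonads, which did not pass (-0.21, adjusted p = 0.442). The 23 families named in advance that the file held, among them mcra of methanogenesis, dsra of sulfate reduction and nifh of nitrogen fixation, had log2 differences of 0.23 to 0.51, and none passed. limma called 0 families, with 44 at an unadjusted p under 0.05. With equal array totals the counts were 0 and 3, and with quantile scaling 0 passed. Without co digester 3, limma called 326 families, without co digester 2 it called 3, without mono digester 3 it called 2 and without mono digester 1 it called 1.

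2 probes passed at the first step, both assigned to Corynebacterium, a genus common in poultry litter. A poba probe of Corynebacterium ammoniagenes, for the hydroxylation of hydroxybenzoate, was higher in co digesters by a log2 of 3.63 (limma adjusted p = 4.6e-05), and by 3.21 with equal array totals (adjusted p = 0.00249). A cysI probe of Corynebacterium stationis, for sulfite reduction, was higher by 2.64 (adjusted p = 0.000997), and by 2.22 with equal totals (adjusted p = 0.0244). The poba probe had a value on 3 of 9 mono and 9 of 9 co arrays of the first step and the cysI probe on 4 and 9, and the other arrays took their lowest value, which sets part of these sizes. With missing values left missing the differences were 3.24 (adjusted p = 0.00203) and 2.38 (0.00351). limma called these 2 among the 41880 tested, with 4497 at an unadjusted p under 0.05. They were named after their values were seen. The other poba probe of Corynebacterium ammoniagenes did not pass (0.67, adjusted p = 0.419, and 0.25 with equal totals), and 1 of the 20 probes of this species passed. Quantile scaling called 4 probes, adding a p450aro probe of the fungus Schizophyllum commune on the higher side and an xlnd probe of Klebsiella pneumoniae on the lower side. The xlnd probe had a value on 3 of 9 mono and 0 of 9 co arrays of the first step, so all its co values were filled. The p450aro probe had a value on 6 and 9, and differed by 0.78 as deposited with missing values left missing (limma adjusted p = 0.55). The genus Corynebacterium as a whole (336 probes) had a log2 difference of 0.53 ± 0.29 (SE, n = 3 digesters per arm, limma adjusted p = 0.311), and genera common in poultry gut and litter took 1.89% of the signal in mono and 1.92% in co digesters (exact permutation p = 0.6, BH-adjusted 0.7). Without mono digester 3 limma called 272 probes, without day 62 it called 21, without the 5 arrays with few probes 8, without mono digester 2 or co digester 2 it called 3, and without co digester 1 it called 1.

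Among 916 genera with at least 5 probes, 12 were higher and none lower in co digesters at the first step. The largest differences were in the bacterium Myroides (log2 1.51 ± 0.29 SE, limma adjusted p = 0.00025), the gut bacterium Coprobacillus (1.26, 0.00585) and the fungus Grosmannia (1.26, 0.00585), against a median of 0.40 over genera. limma called 0 genera with equal array totals (25 at an unadjusted p under 0.05) and 0 with quantile scaling, and 0 with deposited signal when every array was a value with digester as a random block. The 12 became 679 without co digester 3, 6 without mono digester 3 or co digester 2, 2 without mono digester 2 or co digester 1, and 0 without mono digester 1. They became 1 without day 62, 4 without day 66, 7 without day 69, and 1 without the array of co digester 2 on day 62.

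None of the 16 gene lists that could be tested, from carbon fixation to beta-lactamases, stood apart from the other families at the first step by camera (lowest adjusted p = 0.294, for carbon fixation, and 0.991 with an estimated correlation), and fry called 0 of them. No member of any list passed over all families. Adjusted over the list alone, 1 of the 2 mercury families was higher. No category of the file passed camera (lowest adjusted p = 0.898) or fry. Acetate-using methanogens took 0.382% ± 0.048 of the signal in mono and 0.298% ± 0.034 in co digesters (SD, n = 3, exact permutation p = 0.1, BH-adjusted 0.7), a log2 difference of -0.34 that was 0.08 as deposited. Hydrogen-using methanogens took 0.178% and 0.208% (exact permutation p = 0.7), methylotrophic methanogens 0.0109% and 0.0102% (p = 0.5), and syntrophs 0.121% and 0.116% (p = 0.4). Rumen genera took 0.985% in mono and 1.04% in co digesters (exact permutation p = 0.7), and fungi and other eukaryotes 7.17% and 7.33% (p = 0.6).

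At the second step, the mean number of detected probes and the mean Shannon index were higher in co digesters. Mono digesters had 31569 ± 3119 detected probes and co digesters 39509 ± 1246 (SD, n = 3, exact permutation p = 0.1, the smallest that 3 against 3 allows). The Shannon index was 9.34 ± 0.17 in mono and 9.69 ± 0.06 in co digesters (exact permutation p = 0.1). The community profiles also lay apart: the mean Bray-Curtis dissimilarity was 0.105 within mono, 0.078 within co and 0.184 between arms, against 0.085, 0.12 and 0.103 at the first step. The arm took 0.714 of the variance, and the highest of the other splits 0.258 (exact permutation p = 0.1). The summed signal was 598.7 ± 69.8 in mono and 917.6 ± 70.6 in co digesters (in units of 1000000 intensity units, p = 0.1, exact), and the means of the log2 totals differed by 0.72. Without day 87 the difference in detected probes (richness at second step) was 4357 in place of 7940 and that in Shannon index 0.192 in place of 0.346. With the 5 arrays with few probes left out, which were picked by this same measure, so that a smaller difference decides nothing, mono digesters had 37484 ± 2984 and co digesters 39509 ± 1246 (SD, n = 3, exact permutation p = 0.3), and the Shannon index was 9.57 ± 0.06 and 9.69 ± 0.06 (exact permutation p = 0.1).

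Nearly every gene family had a higher deposited signal in co digesters at the second step. limma called 349 of 368 families, all higher, around a median log2 of 0.79 (0.39 without the 5 arrays with few probes, and 0.54 without day 87). With equal array totals, which centres the arrays, the median was 0.08, and 78 families were higher and 29 lower. With quantile scaling 57 were higher and 49 lower, and 46 higher and 25 lower families passed under both scalings. The largest named families were qorl of polycyclic aromatic breakdown (log2 1.99 ± 0.19 SE, 1.20 above the median), fungal dextranase (1.58), the actin families of ciliates (1.56), amoebozoa (1.53) and Cercozoa (1.50), and accD, an acetyl-CoA carboxylase subunit filed under carbon fixation (1.54). With equal totals qorl was higher by 1.55 ± 0.31 (limma adjusted p = 0.0276), dextranase by 1.15 (0.0402) and Cercozoa actin by 1.21 ± 0.11 (0.0145), whereas ciliate actin (0.0808), amoebozoan actin (0.067) and accD (0.0608) did not pass. With quantile scaling the differences were smaller. There qorl (1.08, limma adjusted p = 0.0196) and dextranase (0.54, 0.0454) passed, while Cercozoa actin (0.47, 0.061), the other actin families and accD did not. None of these 6 families has a probe with a value on all arrays. No family passed on the lower side as deposited. There the rule named the carbonic anhydrase family IcfA (-0.03, adjusted p = 0.894), which was lower by -0.74 ± 0.15 with equal totals (adjusted p = 0.0282). The mean of its probes detected on all arrays was higher by 0.43 as deposited, where the log2 totals differed by 0.72. That value is on another scale and does not contradict the lower value with equal totals.

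All 23 families named in advance had a higher deposited signal in co digesters at the second step, by 0.39 (gdh) to 0.91 (nrfa). Relative to the array total, 2 were higher: nrfa, which reduces nitrite to ammonium (0.19 ± 0.04 SE, limma adjusted p = 0.0269), and endoglucanase of cellulose breakdown (0.11 ± 0.03, 0.0448). On the same scale 2 were lower: mcra, the methyl-coenzyme M reductase of methanogenesis (-0.23 ± 0.05, 0.0383, but 0.49 as deposited), and codh, the carbon monoxide dehydrogenase of the acetyl-CoA pathway (-0.26 ± 0.05, 0.024, but 0.47 as deposited). Both kept their sign with quantile scaling (-0.23 and -0.27). The codh family holds a bright probe of Methanosaeta concilii, which was lower by -1.29 with equal totals. Its mean log2 signal over all arrays was 18.2, against a mean log2 of 20.33 for the family sum in mono digesters. The family was not tested without this probe, so its lower value is not separate from that of the species. Without the 5 arrays with few probes, limma called 164 families as deposited and 1 with equal totals. The 107 families called with equal totals became 45 without mono digester 1, 61 without co digester 3, and 0 without mono digester 2, co digester 1 or co digester 2.

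**Figure D2:**
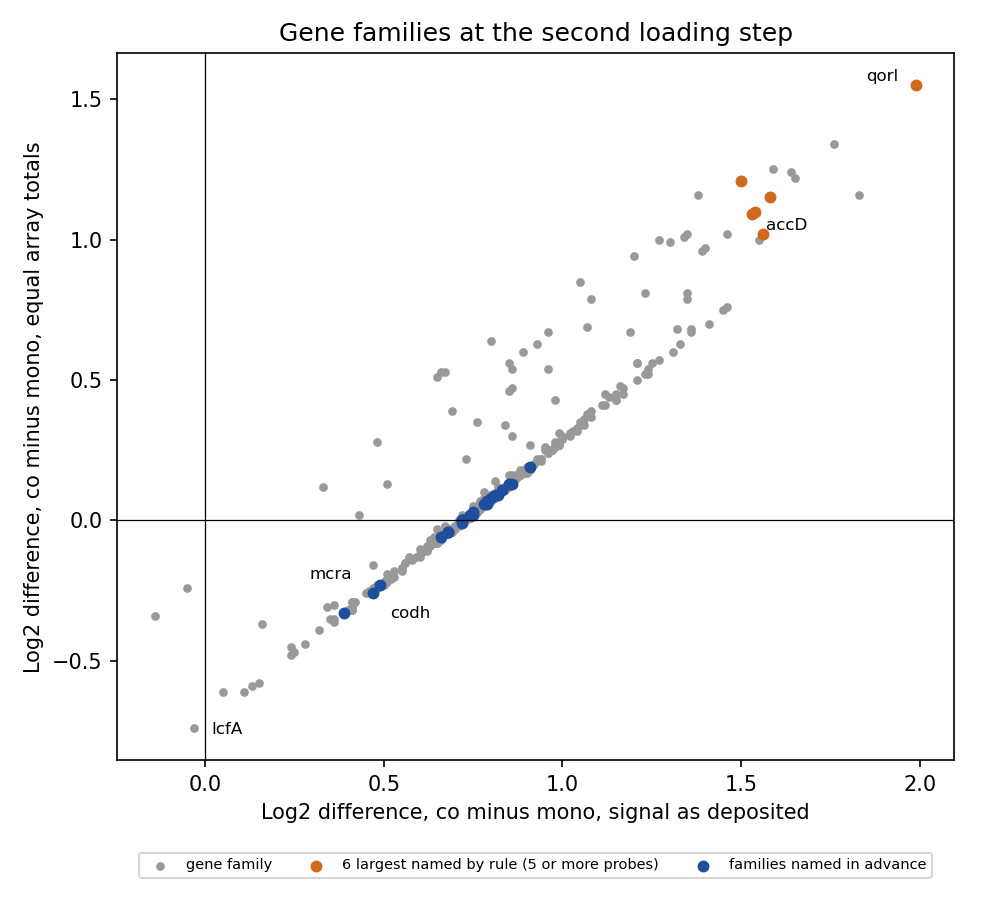
Log2 difference of each of 368 gene families at the second step, co minus mono, with the signal as deposited (horizontal axis) and with equal array totals (vertical axis). Most families lie right of 0 on the first scale, at a median of 0.79, and spread around 0 on the second, at a median of 0.08.

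Gene lists fixed in advance moved with the rest of the array at the second step. All members were higher as deposited for ammonification and nitrogen assimilation (7 of 7), sulfur oxidation (7 of 7), denitrification (6 of 6), starch degradation (6 of 6), sulfate and sulfite reduction (5 of 5), chitin degradation (5 of 5), nitrification and anammox (5 of 5), cellulose degradation (4 of 4), hemicellulose degradation (4 of 4), beta-lactamases, phosphorus and other metals (3 of 3 each). Carbon fixation had 10 of 11 higher, pectin degradation 9 of 10, lignin and aromatic plant carbon degradation 8 of 9, and arsenic 4 of 5. The file places 6 of these 9 under lignin or vanillin, limeh and lmo under terpenes and camdcab under camphor, and camdcab was the family that did not pass (0.11, adjusted p = 0.565). Adjusted over the list alone, these counts were the same. The lists with fewer than 3 families were not tested as sets: acetogenesis (2 of 2 higher), methane oxidation (2 of 2), mercury (2 of 2), and 1 family each for methanogenesis, nitrogen fixation and copper, all higher. The only family of the list fixed for antibiotic efflux was fosa, which inactivates fosfomycin and is no pump, and it was higher. camera called 0 of the 16 lists (lowest adjusted p = 0.846, and 0.967 with an estimated correlation), with none with equal totals, while fry, which does not compare a list with other families, called 16.

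With equal array totals, members of the lists parted at the second step. Lignin and aromatic plant carbon degradation had 3 families higher and 1 lower (5 and 1 adjusted over the list alone): ligninase (0.45), the manganese peroxidase mnp (0.22) and the terpene family limeh (0.14) were higher, and camdcab of camphor breakdown was lower (-0.61). Among the other lists, cellulose degradation had 2 higher and 0 lower (3 and 0), and pectin degradation 1 and 1 (1 and 1). Carbon fixation had 2 higher and 2 lower (2 and 2). 1 of its lower families was codh, which is also the lower family of acetogenesis and holds the bright Methanosaeta concilii probe. Ammonification, denitrification, and nitrification and anammox each had 1 higher and 0 lower (1 and 0 adjusted over the list alone). Starch and chitin degradation each had 0 higher and 1 lower (0 and 0), sulfur oxidation 0 and 1 (0 and 1), and beta-lactamases 0 and 1 (1 and 1). In arsenic, hemicellulose, phosphorus, other metals, and sulfate and sulfite reduction 0 families passed by limma. Of the small lists, acetogenesis (codh, with its bright Methanosaeta concilii probe) and methanogenesis (mcra) had 1 lower family each. Mercury and copper had 1 higher family each, fosa was also higher, and methane oxidation and nitrogen fixation had none. Adjusted over the list alone, both methane oxidation families were higher and acetogenesis had 1 higher and 1 lower. Of 51 categories of the file, camera called 2, which hold the same 27 phylogenetic marker families of eukaryotes, such as actin and elongation factor genes: 25 of 27 were higher, at a median of 0.26 above the median family (adjusted p = 0.00757). The call was lost with an estimated correlation (adjusted p = 0.998) and with equal totals (adjusted p = 0.479), and fry called 50 of the 51.

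Acetate-using methanogens took a smaller share of the signal in co digesters at the second step. Their 78 probes held 0.488% ± 0.10 of the signal in mono and 0.221% ± 0.027 in co digesters (SD, n = 3, exact permutation p = 0.1, BH-adjusted 0.233), a log2 difference of -1.08 (-0.36 as deposited). The genus Methanosaeta, whose members live on acetate, was lower by -0.51 ± 0.21 as deposited (limma adjusted p = 0.0185), by -1.24 ± 0.17 with equal totals (adjusted p = 0.0273) and by -1.21 with quantile scaling (adjusted p = 0.023). Methanosarcina, the other acetate-using genus on the list, had a log2 difference of 0.14 with equal totals (adjusted p = 0.269), 0.86 as deposited and -0.02 with quantile scaling. Hydrogen-using methanogens took 0.175% in mono and 0.177% in co digesters (exact permutation p = 0.4), methylotrophic methanogens 0.0106% and 0.0133% (p = 0.1, BH-adjusted 0.233), and syntrophs, the bacteria that pass hydrogen to methanogens, 0.117% and 0.127% (p = 0.1, BH-adjusted 0.233). Genera of poultry gut and litter took 1.87% and 1.85% (exact permutation p = 0.5), rumen genera 0.974% and 0.971% (p = 1), and fungi and other eukaryotes 7.13% and 7.29% (p = 0.2). 7 lists were compared per step.

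**Figure D3:**
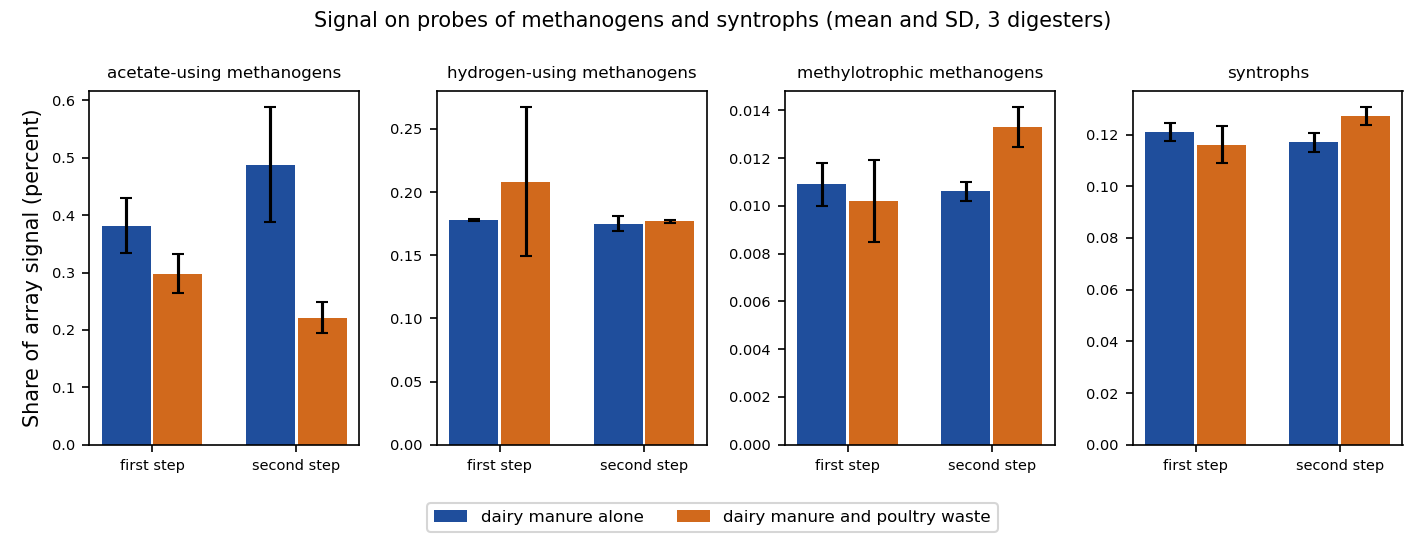
Share of the array signal (percent, vertical axes starting at 0, each panel on its own scale) on probes of 4 organism lists at the first and second step; bars are means of 3 digesters and whiskers the SD. Acetate-using methanogens stand at 0.488% in mono and 0.221% in co digesters at the second step, most of it on the 8 probes of Methanosaeta concilii.

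The lower Methanosaeta signal lay in Methanosaeta concilii. Its 8 probes, in the families amyA, arsc, codh, dsra, gdh, nifh and rubisco, were all lower in co digesters at the second step with equal totals, by a log2 of -0.81 (arsc) to -1.68 (dsra), each past the limma test. As deposited 7 of the 8 passed, and arsc did not (-0.09, limma adjusted p = 0.755). The 8 probes held 4250 ± 1100 ppm of the signal in mono and 1530 ± 280 in co digesters (SD, n = 3), and the mean log2 share was lower by 1.41, a ratio of geometric means of 2.66 (exact permutation p = 0.1). At the first step the shares were 3180 ± 510 and 2310 ± 310 (exact permutation p = 0.1). In deposited signal the mean log2 differed by -0.69 at the second step and by -0.02 at the first, where the plain means were 2340 in mono and 2670 in co digesters (in units of 1000 intensity units). Without the array of co digester 2 on day 62 the first-step difference was -0.24 in deposited signal (exact permutation p = 0.5) and -0.36 in share (p = 0.2). The species had the lowest median of 1371 species with at least 5 probes at both steps and in the change between them, and it was named after its values were seen. Probes of Methanosaeta harundinacea and Methanosaeta thermophila had medians of -0.28 and 0.25 at the second step with quantile scaling, against -1.32 for Methanosaeta concilii.

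**Figure D4:**
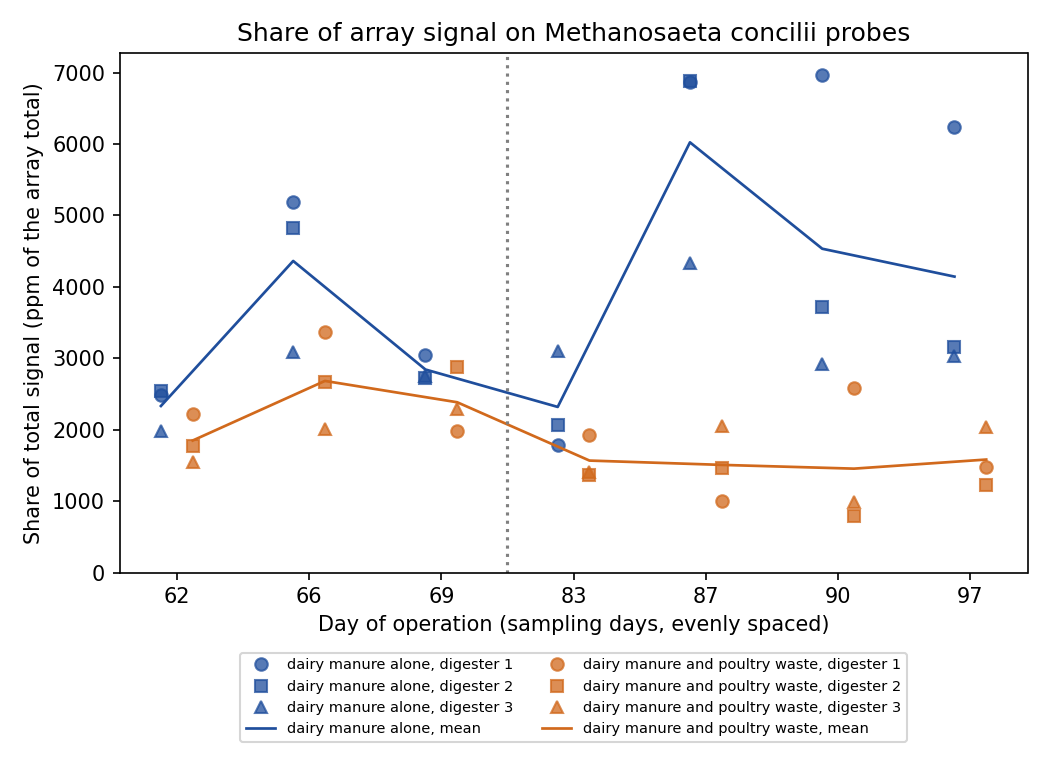
Share of the array signal on the 8 Methanosaeta concilii probes (ppm of the array total, vertical axis) by sampling day (horizontal axis, days evenly spaced), with 1 point per digester and a line through each arm's mean. On days 87, 90 and 97 all mono digesters lie above all co digesters, and on day 83 the arms overlap, with mono from 1787 to 3106 and co from 1369 to 1929. The highest mono points (6864 to 6965 ppm) lie on arrays whose totals were 0.26 to 0.38 times the median array's.

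At the level of single probes, 20562 of 41880 (49.1%) passed limma at the second step, 19923 higher and 639 lower in co digesters. With equal array totals 5568 were higher and 14978 lower, a count that includes probes whose filled lowest values moved with the totals. Of the 10058 probes with a value on all arrays, 2524 were higher and 3479 lower with equal totals, and over all probes with quantile scaling 9511 were higher and 8486 lower. 5369 higher and 7676 lower probes passed under both scalings. Of 916 genera, limma called 846 higher and 2 lower as deposited (Methanosaeta and Catenibacterium, the latter at -0.52 with an adjusted p of 0.0161), 157 higher and 44 lower with equal totals, and 103 higher and 104 lower with quantile scaling. Without the 5 arrays with few probes, the equal-totals counts were 17034 probes and 0 genera, and the deposited counts 16718 probes and 251 genera. Without day 87, 479 genera passed as deposited. The 20546 probes with equal totals became 12844 without mono digester 2 and 12624 without co digester 2. The 201 genera became 16, 1 and 305 without mono digesters 1, 2 and 3, and 0, 2 and 31 without co digesters 1, 2 and 3.

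Much of the probe-level difference at the second step followed an axis on which arrays of a single arm already differed. The main axis of the 9 first-step co arrays held 40.9% of their variance over 10058 probes, and across these probes it correlated with the second-step difference between arms (Pearson r = 0.85, Spearman rho = 0.86). Probes are not independent replicates, and this axis was examined after the results were seen. With the first-step difference r was -0.31. Mono arrays took scores of -20.7 to -21.7 in digesters 1 and 2 on day 66 and of -28.6 to -47.3 on day 90. Co digester 3, with -22.4 on day 69 and -20.3 on day 97, also lay on that side. The labels give no hybridisation batch, so no value within batches can be had.

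**Figure D5:**
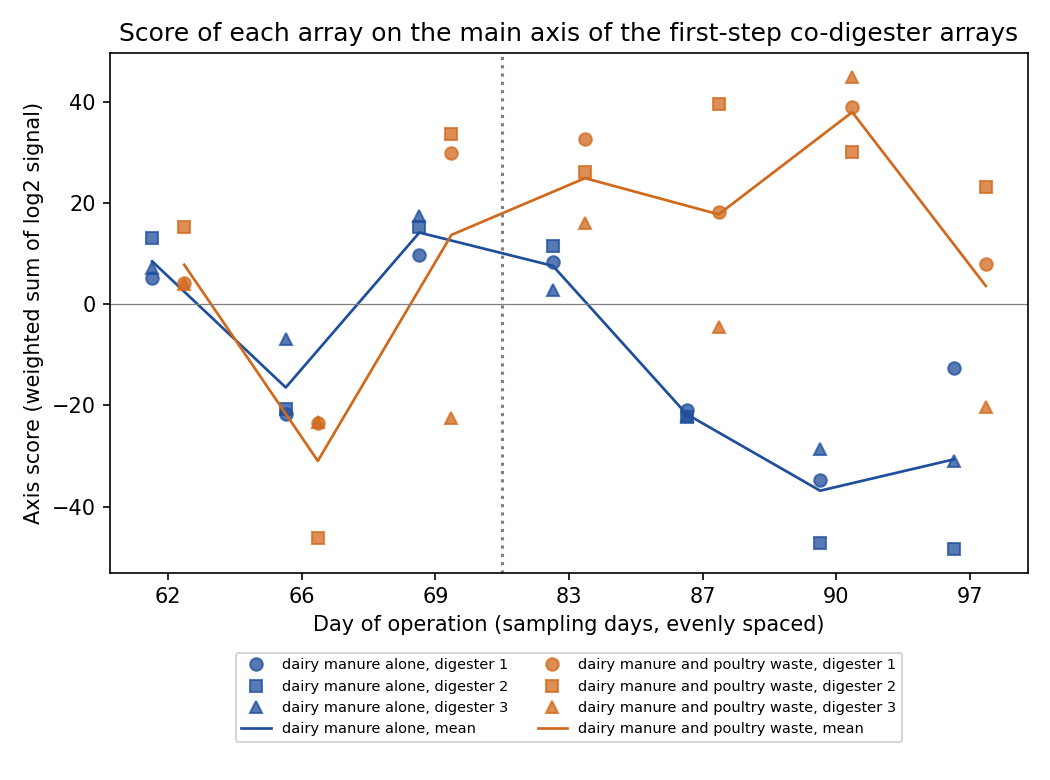
Score of each array (vertical axis, weighted sum of centred log2 signal) on the main axis of the 9 first-step co arrays, by sampling day (horizontal axis, days evenly spaced), with 1 point per digester and a line through each arm's mean. On day 66 all arrays of both arms lie below 0, and on day 90 co arrays lie at 30.1 to 45.1 and mono arrays at -28.6 to -47.3.

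Between the steps, the change in detected probes was 3994 ± 1778 in co and -2643 ± 2086 in mono digesters (SD, n = 3, exact permutation p = 0.1), and the change in the Shannon index was 0.215 ± 0.165 and -0.122 ± 0.061 (exact permutation p = 0.1). When the 5 arrays with few probes were left out, detected probes changed by 2629 ± 1066 in co and 1795 ± 3512 in mono digesters (exact permutation p = 0.8), which decides nothing on the fall in mono digesters, since 4 of those arrays were mono and picked by this measure. The change in the Shannon index was then 0.089 ± 0.057 and 0.050 ± 0.092 (exact permutation p = 0.6). In deposited signal, 327 of 368 families fell and 1 rose in mono digesters, around a median log2 of -0.47, with each digester compared with itself. With every array as a value and digester as a random block limma called 0 in mono (90 at an unadjusted p under 0.05) and 0 in co digesters (14), and with steps as independent values 20 and 0. In co digesters 7 rose and 7 fell, around a median of -0.09, but 30 rose and 2 fell (median 0.20) without the array of co digester 2 on day 62, and 8 rose and 110 fell (median -0.19) without co digester 3. With equal totals limma called 9 falling families in mono digesters, and 21 rising and 4 falling in co digesters. With quantile scaling it called 0 in mono (328 as deposited at an unadjusted p under 0.05), and 11 rising and 13 falling in co digesters. The 328 in mono digesters became 13 without day 62, 4 without day 69, 9 without day 87 and 15 without the 5 arrays with few probes. The 14 in co digesters became 118, 24 and 0 without co digesters 3, 1 and 2, 30 without any single mono digester, 2 without day 66, 27 without day 69, 30 without day 97, and 32 without the array of co digester 2 on day 62.

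The change differed between the arms for 139 families, 138 of them with a higher change in co digesters, around a median log2 of 0.37 (limma, 205 at an unadjusted p under 0.05). The median was 0.66 without the array of co digester 2 on day 62, 0.14 without day 87 and 0.10 without the 5 arrays with few probes. With every array as a value and digester as a random block 0 families passed (34 at an unadjusted p under 0.05), and with steps as independent values 5. The largest were qorl (1.64 ± 0.16 SE, adjusted p = 3.33e-05), ciliate actin (1.21), fungal dextranase (1.15), amoebozoan actin (1.10), accD (1.07) and MMCE_3HP4HB of carbon fixation (1.04). IcfA had a lower change (-0.60 ± 0.18, adjusted p = 0.0251). With equal totals qorl (1.60, adjusted p = 0.00707), dextranase (1.11, 0.0271), amoebozoan actin (1.05, 0.0451) and IcfA (-0.90, 0.0257) passed, and ciliate actin (0.167), accD (0.0936) and MMCE_3HP4HB (0.134) did not. The next on the lower side, pcpA (-0.59, adjusted p = 0.089) and pel_Cdeg of pectin breakdown (-0.14, 0.55), did not pass. Of the 23 families named in advance, 5 had a higher change in co digesters: nrfa (0.68), fthfs of acetogenesis (0.47), endoglucanase (0.44), arsc of arsenate reduction (0.43) and cellobiase (0.41). limma called 0 of them with equal totals.

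The count of families with a different change depended on the scaling and on single days. limma called 39 with equal totals (36 higher, 3 lower) and 34 with quantile scaling (19 higher, 15 lower). The 139 became 63, 59 and 70 without mono digesters 1, 2 and 3, and 221 without co digester 2. They became 50, 11, 23, 257, 11 and 55 without days 62, 66, 69, 83, 87 and 90, and 237 without the array of co digester 2 on day 62. Without the 5 arrays with few probes 11 families passed, and 0 with equal totals. The 39 became 22, 20, 26, 26 and 14 without mono digesters 1 and 2 and co digesters 1, 2 and 3.

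Methanosaeta concilii probes also differed in their change. Their share of the signal had a log2 change of 0.34 ± 0.17 in mono and -0.63 ± 0.36 in co digesters (SD, n = 3, exact permutation p = 0.1), a difference of -0.98. The rise in mono digesters was one of share only, since their deposited signal was 2340 at the first and 2220 at the second step (in units of 1000 intensity units). The highest mono shares, 6864 to 6965 ppm, lay on arrays of days 87 and 90 whose totals were 0.26 to 0.38 times the median array's. With equal totals 7 of the 8 probes passed the limma test of the change, with amyA at -1.13 and -0.81 and dsra at -1.15, and arsc did not pass (-0.53, adjusted p = 0.0903). As deposited 0 of the 8 passed (lowest adjusted p = 0.0551, with amyA at -0.82). The 7 became 2, 0 and 3 without mono digesters 1, 2 and 3, 7, 2 and 6 without co digesters 1, 2 and 3, and 2 without the 5 arrays with few probes, with all 8 differences below 0 each time. At the second step all 8 passed in each of these runs with equal totals. The 8 probes read 1 species on the same arrays, so they are not 8 independent results. By digester the second-step share had an exact permutation p of 0.1. Single days were not left out for these counts, and on day 87 the mean share was 6020 ppm in mono and 1510 in co digesters. The genus Methanosaeta had a difference in change of -0.84 ± 0.17 with equal totals (adjusted p = 0.048), of -0.83 with quantile scaling (0.0467) and of -0.54 as deposited (0.0906). Methanocorpusculum, a hydrogen-using genus picked after its values were seen, had a higher change in co digesters by 0.91 ± 0.16 as deposited (adjusted p = 0.00834), 0.64 ± 0.10 with equal totals (0.0282) and 0.41 with quantile scaling (0.0413). The list of hydrogen-using methanogens fixed in advance had a log2 difference in share of 0.13 at the first step and 0.02 at the second.

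Over all probes, 10886 differed in their change, 9845 with a higher and 1041 with a lower change in co digesters, and 11982 with equal totals (5286 higher, 6696 lower) or 17221 with quantile scaling (8814 and 8407). With every array as a value and digester as a random block 1 probe and 0 genera passed (9913 and 82 at an unadjusted p under 0.05). Over genera the counts were 320 higher and 3 lower (Heterobasidion, Heterosigma and Serpula), 54 and 7 with equal totals, and 53 and 45 with quantile scaling. The 10886 probes became 7052, 5398 and 6452 without mono digesters 1 and 3 and co digester 3, and 290, 13, 6999 and 4606 without days 66, 69, 87 and 90. Without the 5 arrays with few probes 17 passed, and 11085 with equal totals. The 11982 became 5603, 2, 7006, 3403 and 4096 without mono digesters 1, 2 and 3 and co digesters 2 and 3. The 323 genera became 203, 140 and 171 without mono digesters 1, 2 and 3, 536 and 195 without co digesters 2 and 3, and 560 without the array of co digester 2 on day 62. They became 168, 11, 15, 551, 24 and 0 without days 62, 66, 69, 83, 87 and 90, and 15 without the 5 arrays. The 61 genera with equal totals became 38 without mono digester 3, and 0 without any other single digester or without the 5 arrays.

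None of the 16 gene lists stood apart in its change by camera (lowest adjusted p = 0.93, and 0.961 with an estimated correlation), and fry called 0. Cellulose degradation had 4 of 4 families with a higher change in co digesters (4 adjusted over the list alone), lignin and aromatic plant carbon degradation 5 of 9 (6), ammonification and nitrogen assimilation 3 of 7 (5), arsenic 3 of 5 (3), pectin degradation 3 of 10 (3) and carbon fixation 2 of 11 (2). Chitin degradation and beta-lactamases had 1 each (1 each), and hemicellulose degradation 1 of 4 (0). In denitrification, nitrification, phosphorus, other metals, starch degradation, sulfate and sulfite reduction and sulfur oxidation 0 passed. Of the small lists, acetogenesis, methane oxidation, mercury and copper had 1 each, fosa also passed, and methanogenesis and nitrogen fixation had 0. In lignin and aromatic plant carbon degradation the 5 were glx, ligninase, mnp, phenol_oxidase and the terpene family limeh. With equal totals carbon fixation and lignin degradation had 1 each and the other lists 0. No category passed camera (lowest adjusted p = 0.973) or fry.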

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

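The tests of scaling for all 3 patterns, of the array axis and of species for the wide second-step difference and for that axis, and of the other splits of the digesters were chosen after the results were seen.

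The share of signal on Methanosaeta concilii probes was lower in co digesters at the second step, and 7 of its 8 probes differed between the arms in their change over the steps with equal totals (0 as deposited, and 0 without mono digester 2). A median below 0 under all 3 scalings (at highest -0.71, as deposited) decides nothing by itself, since the species was picked by its low median. A factor per array moves all probes of the array together, and the median over all probes was 0.45 as deposited. By itself this contrast decides nothing, since a distance from the other probes picked the species. Of 10000 random probe sets of like brightness, 0% had as low a median (lowest -0.5, against -1.32, with quantile scaling). These sets outnumber the 1371 species, so picking the lowest species does not alone make this gap. The tables thus argue against compression of bright probes, and against a factor per array as the whole cause. Noise shared by the probes of 1 species is not covered by such sets. The axis on which arrays differ within an arm is also argued against as the whole cause. The median was -1.16 after the part along that axis was removed (-1.31 before). A smaller population of this acetate-using methanogen in the co digesters is a candidate explanation, found and tested on the same data. Poultry waste and the higher loading stay open as its source, untested, because both came together.

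Nearly all families, 20562 probes and 848 genera had a different signal at the second step. The family median of 0.08 with equal totals decides nothing on a difference in total signal, because dividing by totals centres the arrays, and this stays open for families; 1 factor per array as the whole cause is argued against for probes, since 6003 of the 10058 with a value on all arrays passed with equal totals. An array axis already present among the first-step co arrays may account for most of the spread between probes, since it correlated with the second-step difference at 0.85 across probes. Of the probe variance 1.24% lay between species, above the highest of 100 shuffles (0.61%), so some species structure was present. So small a share argues against organisms changing in abundance as the whole cause only if probe assignments to species hold and probe noise is small. Neither was measured. Species took 1.3% of the variance of the axis loadings (highest of 100 shuffles 2.01%), which argues against them there under the same conditions. What made the axis stays open, since no batch is given, and feed and loading stay open too.

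Probes of Brachybacterium faecium, a bacterium first isolated from poultry litter, had the highest species median in co digesters at the first step, at 345 ± 5.7 against 277 ± 8.4 ppm (SD, n = 3, exact permutation p = 0.1). The lowest median of 0.35 over the log2 differences of its probes under 3 scalings decides nothing on scaling, which stays open, because the species was picked by this median. The tables argue against a single digester by another measure, the difference between arms in the digesters' median over these probes, which was at lowest 0.54 when each digester was left out in turn (Brachybacterium faecium at first step, 0.60 with all). A shift of all Actinobacteria is argued against by the median of -0.01 over their other 5327 probes, and no single probe of the 12 passed limma. Carry-over of this bacterium with poultry waste is a candidate explanation that was not tested apart from loading.

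The first-step arrays were tested for a sample far from the others, in 6 groups of 9. Chance gives about 1 in 20 for independent arrays, but these were repeated samples of 3 digesters. The total signal of co digester 2 on day 62 stood apart at 3840 (in units of 1000000 intensity units). Second-step arrays were not tested in this way, though the fewest detected probes of all (11398) lay there, in mono digester 2 on day 87. Co digester 1 on day 66 stood apart with 25075 detected probes and a Shannon index of 8.51. The difference between arms changed between the steps for 139 families. It changed for 10886 probes. It changed for 323 genera.

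The 6 digesters allow 10 splits, too few for a share under 0.05. At the second step 349 families, 20562 probes and 848 genera passed, and the highest of the other splits gave 0 in each case, so 1 split of the 10 was as large. With equal totals these were 107, 20546 and 201 against 0. For the change they were 139 against 0, 10886 against 0 and 323 against 1. At the first step 0 families and 2 probes passed, against 109 and 3558 in the highest of the other splits, and all 10 splits gave as many. For first-step genera 12 passed, against 59, and 3 splits gave as many. Splits that call so many more than the real one point to a structure of the samples, which was not tested, and without co digester 3 alone the real split gave 326 families. For gene lists 0 passed against 1 in each comparison. For categories it was 0 against 2 at the first step, 2 against 5 at the second (5 splits as large) and 0 against 3 in the change. The changes within an arm allow 4 sign turns, also too few, with 14 families against 0 in co and 328 against 0 in mono digesters.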

How the results depend on the processing

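The runs without the 5 arrays with few probes, the run without the array of co digester 2 on day 62, all runs on genera except equal totals, and all runs on named species were chosen after the data were seen. Outside the named families, 419 of 631 alternative values stayed within the spread or within 1.5 times the count, 205 moved and 7 reversed. For named families 1692 of 2032 stayed on their side of the threshold, 224 lost it, 80 gained it and 36 reversed. Part of what stayed was fixed in advance, so these shares do not measure robustness. At the first step, where no named family had passed, 529 of 565 values stayed. Leaving out a day-62 array cannot move a second-step value. Equal totals cannot move detected probes, the Shannon index or the dissimilarity of relative signals. A value of a named family that changed sign without passing a test under either setting was not counted as reversed. Among the organism lists only acetate-using methanogens are given in full. Signal over background is not given, so dim probes limit the families with few of them. Except where a setting uses fewer arrays or families by its construction, the cause was not tested.

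Equal totals changed the families at second step from 349 to 107, families change difference from 139 to 39, families change in co digesters from 14 to 25 and families change in mono digesters from 328 to 9. Quantile scaling gave 106, 34, 24 and 0. With equal totals the second-step log2 was -0.04 for ara, 0 for chitinase, -0.26 for codh, -0.33 for gdh, -0.23 for mcra, -0.06 for narg, -0.04 for nifh, 0 for nirk, 0 for ppx and -0.01 for urec. With quantile scaling it was 0 for amyA, -0.05 for ara, -0.27 for codh, -0.32 for gdh, -0.23 for mcra, -0.02 for narg, -0.04 for nifh, 0 for norb and -0.02 for urec. With the mean log2 of probes on all arrays, in deposited signal, IcfA was 0.43 at the second step and 0.07 in the change, and pel_Cdeg was 0.47 in the change. In that setting 2 families passed at the first step and 59 in the change in co digesters. Restricting the test to families on all arrays gave 5 at the first step and 22 in the change in co digesters, and a pseudocount 10 times larger gave 6 at the first step.

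With every array as a value and digester as a random block, 0 families passed in the change difference, in co and in mono digesters, 1 probe in the change difference, and 0 genera at the first step and in the change difference. The consensus correlation was -0.004 for families, 0.008 for probes and -0.003 for genera. With steps as independent values (no replicate block) 5 families passed in the change difference, 0 in co and 20 in mono digesters. With the digester number as a replicate block, 0 families passed at the first step, 334 at the second and 112 in the change difference, 149 probes at the first step, 19739 at the second and 3732 in the change, and 3 genera at the first step. Digesters with the same number were not more alike across arms at the second step, with correlations over families of -0.01, -0.08 and -0.11 (0.36, -0.01 and 0.01 at the first step). So few values show no pairing by number but cannot exclude it.

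The change difference of families was 50, 11, 23, 257, 11 and 55 without days 62, 66, 69, 83, 87 and 90. The change in co digesters was 2, 27 and 30 without days 66, 69 and 97, and that in mono digesters 13, 4 and 9 without days 62, 69 and 87. Probes at the first step were 21 without day 62, and in the change difference 290, 13, 6999 and 4606 without days 66, 69, 87 and 90. Genera at the first step were 1, 4 and 7 without days 62, 66 and 69, at the second step 479 without day 87, and in the change difference 168, 11, 15, 551, 24 and 0 without days 62, 66, 69, 83, 87 and 90.

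Without the 5 arrays with few probes, families were 3 at the first step, 164 at the second, 11 in the change difference and 15 in the change in mono digesters. Probes were 8 at the first step and 17 in the change difference, and genera 251 at the second step and 15 in the change difference. With equal totals as well, families were 1 at the first step, 1 at the second, and 0 in the change difference, in co and in mono digesters, and genera 0 at the first step, the second step and the change difference. In that setting the second-step log2 was -0.03 for ara, -0.02 for chitinase, -0.22 for codh, 0 for dsra, -0.11 for gdh, -0.20 for mcra, -0.02 for narg, -0.07 for nifh, -0.04 for nirk, -0.02 for norb, -0.01 for ppx, -0.01 for urec and -0.01 for xylanase, and cellobiase was -0.01 in the change. Without the array of co digester 2 on day 62, 237 families and 560 genera passed in the change difference, 32 families in the change in co digesters and 1 genus at the first step.

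For probes, quantile scaling gave 4 at the first step and 17221 in the change difference, probes on all arrays 0, 6276 at the second step and 4499, no filter 1 at the first step, and missing values left missing 6 and 2830. For genera, equal totals gave 0, 201 and 61 at the first step, second step and change difference, and quantile scaling 0, 207 and 98. fry called 16 lists and 50 categories at the second step, where camera called 0 and 2, and camera on categories gave 0 with an estimated correlation and 0 with equal totals. Values of named species in this part are differences between arms in each digester's median over the probes of the species, not the share of signal or the median of probe differences given elsewhere. Corynebacterium ammoniagenes, at -0.03 at the second step with equal totals, was 0.69 as deposited, 0.31 with quantile scaling and 0.28 without the 5 arrays, and its change (-0.29) was 0.01 as deposited. The change of Brachybacterium faecium (-0.16) was 0.14 as deposited. Methanosaeta concilii at second step was -1.56 with equal totals, -0.83 as deposited, -1.35 with quantile scaling and -1.23 with equal totals without the 5 arrays. Without those arrays detected probes (richness at second step) differed by 2025.2 in place of 7940.5 and Shannon at second step by 0.11 in place of 0.346, with the arrays picked by their detected probes. The acetate-using methanogen share was -0.86 without those arrays (-1.08 with them). These 5 arrays were first also weighed as an explanation of the lower Methanosaeta concilii signal and of the wide second-step difference, and after the values were seen they were left to this part.

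Leaving out 1 digester at a time gave ranges of 0 to 326 for families at the first step, 318 to 353 at the second, 59 to 221 in the change difference, 0 to 118 in the change in co and 270 to 325 in mono digesters, and with equal totals 0 to 118 at the second step and 14 to 34 in the change difference. For probes they were 1 to 272, 16880 to 20814 and 5398 to 13346, and with equal totals 12624 to 23351 at the second step and 2 to 12592 in the change difference. For genera they were 0 to 679, 778 to 869 and 140 to 536, and with equal totals 0 to 305 and 0 to 38. Detected probes (richness at first step and richness at second step) differed by -377.67 to 2462.8 and 6838.8 to 9725, Shannon at first step and Shannon at second step by -0.0828 to 0.113 and 0.264 to 0.431, and the PERMANOVA share was 0.173 to 0.287 and 0.676 to 0.788. The share of the acetate-using methanogens was -0.44 to -0.24 and -1.18 to -0.94 (acetate-using methanogens, share of array total, second step), Methanosaeta concilii at second step -1.71 to -1.37, and Corynebacterium ammoniagenes at the second step -0.27 to 0.12.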

Other observations

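The organisms and categories below were picked after their values were seen, and no test beyond those of the report was planned for them.

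Some genera with a higher second-step signal in co digesters passed limma with deposited signal, with equal totals and with quantile scaling, and the higher ones named here are examples. With equal totals Clavispora was higher in co digesters by a log2 of 1.91 ± 0.48 (SE, adjusted p = 0.0457), Meyerozyma by 1.73 ± 0.36 (0.0362) and Neocallimastix by 1.69 ± 0.45 (0.0493), while the list of fungi and other eukaryotes fixed in advance took 7.13% of the signal in mono and 7.29% in co digesters (exact permutation p = 0.2). Among bacteria Dictyoglomus was higher by 1.68 ± 0.23 (0.0273) and Aequorivita by 1.67 ± 0.10 (0.00533). Lower with equal totals and with quantile scaling, but not as deposited, were Peptoniphilus, an anaerobic coccus (-0.60 ± 0.08, adjusted p = 0.0273, but 0.07 as deposited), and Candidatus Protochlamydia (-0.66 ± 0.10, 0.0299, but 0.02 as deposited). Without the 5 arrays with few probes 0 genera passed with equal totals (limma).

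Shares of whole categories differed little. Cellulose genes took 1.81% ± 0.05 of the signal in mono and 1.99% ± 0.05 in co digesters at the second step (SD, n = 3), lignin genes 1.27% ± 0.04 and 1.44% ± 0.06, and methanogenesis genes 0.518% ± 0.031 and 0.44% ± 0.015 (exact permutation p = 0.1 for each). At the first step the cellulose shares were 1.87% and 1.87%, and the methanogenesis shares 0.505% and 0.464%. Of 98 overlapping shares tested, 56 had fully separated arms at the second step and 11 at the first, where chance gives 10%, and the lowest BH-adjusted value was 0.175.

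Single species other than Methanosaeta concilii also had probes on 1 side at the second step. With quantile scaling this held for all probes of 22 of 1371 species, against 23 at the first step. One-sidedness was thus no more common at the second step. Kytococcus sedentarius, Polyporus brumalis and Butyrivibrio crossotus were taken from the ends of the ranking. All 5 probes of Kytococcus sedentarius, an actinobacterium, were higher with equal totals (median log2 0.72), and 6 of 7 probes of the wood fungus Polyporus brumalis (0.82). All 5 probes of Butyrivibrio crossotus were lower (-1.09), of which 3 passed with quantile scaling (median -0.61, and -0.37 as deposited). Of 12 Brachybacterium faecium probes, urec (1.31), terc (1.23) and xyla (0.70) passed limma at the second step with equal totals, and the species share was 263 ± 18 ppm of the signal in mono and 385 ± 11 in co digesters (SD, n = 3, exact permutation p = 0.1).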
